A study of Mus musculus with 3 samples.

How the data were processed

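The deposited values are raw UMI counts per cell and gene, corrected for sequencing errors in the UMI, as written per the file headers by the BD WTA Rhapsody Analysis Pipeline 1.8 with a STAR index of the mouse genome. The submitters' processing notes name the build mm10; the gene annotation and any filter on cells after the pipeline are not given in the sources used here. BD Rhapsody is a microwell method: each cell settles in a well with a bead whose oligonucleotides carry a cell barcode and a UMI, so amplified copies of a molecule are counted once. The values were used as counts, without further correction for free RNA, and the sequencing reads were not used here. The 3 tables hold 24638, 24433 and 23355 gene columns (control, day 14, day 28), with 21234 genes in every table and 27049 in at least 1. A gene missing from a table was taken as 0 there, which among the named genes applies to Mucl1 in the control library alone. The day 28 table carries a later analysis date in its header than the other tables, with the same pipeline version, and library, processing run and group cannot be told apart.

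The tables held 15076 control, 10314 day 14 and 16103 day 28 barcodes with 57066557, 87171019 and 90031231 UMIs. Barcodes with at least 300 genes and under 25% mitochondrial UMIs were used, which removed 24.2% of control, 2.22% of day 14 and 5.33% of day 28 barcodes; 3220 of the 3642 removed from control had too few genes. Scrublet, as run by scanpy 1.11.5 with an expected doublet rate of 6%, then removed 194, 83 and 207 barcodes (1.70%, 0.823% and 1.36%). The 11240, 10002 and 15038 cells left have a median of 3355, 5294 and 3915 UMIs, 1598, 2137.5 and 1773 genes and 6.11%, 6.10% and 6.00% mitochondrial UMIs. How many doublets this step missed, and how many single cells it removed, was not measured.

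Cells of the 3 libraries were clustered together without batch correction: counts scaled to 10000 per cell, log-transformed, 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 1 (leidenalg 0.10.2). Genes of the response lists that are not cell type markers were left out of the clustering. A cluster took the name of the class with the most markers among its 25 genes of highest fold against the other cells, with at least 3 markers required, from 31 marker lists. The markers, the 26 gene lists, the filters, the comparisons and the alternatives of the first set were fixed before the data were examined. The naming rule was not: 2 rules were tried, and the rule in use, with its merging of type 1 with type 2 alveolar cells and of smooth muscle or myofibroblast with pericyte markers, was set after the clusters had been seen. The first rule leaves cluster 10 (T cell in the rule in use) and cluster 23 (mural) unnamed and calls cluster 19 type 2 alveolar and cluster 28 smooth muscle or myofibroblast. Results planned for type 2 alveolar cells are therefore given for a merged alveolar epithelial class. Cluster 17 (480 control, 38 day 14 and 99 day 28 cells), with as many mural as capillary endothelial markers, and cluster 31 (21 cells), with neutrophil and B cell markers, stayed unnamed. Each class is a set of clusters that resemble the named cell type in their markers, not sorted cells.

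Levels are given as CPM, the UMIs of a gene as a share of all UMIs summed over the cells of a class in 1 library. With 1 library per group there is no test between groups, and no p-value or standard error was computed. Ratios of CPM and of shares carry exact 95% conditional (Clopper-Pearson) intervals, which hold counting error only: the spread between mice, which were pooled, and between libraries is not in them. A list member was measured with at least 20 UMIs over the pair of libraries and counted as higher or lower when its ratio was at least 1.5-fold with an interval that excludes 1. A list's median log2 ratio was placed among 10000 random lists of equal size and like mean expression; the percentile describes these libraries and is no test between groups of mice. Where 1 library has no count, it was set to a floor of 3 counts over the class and the ratio is written as a bound. Classes with fewer than 50 cells in a library were not compared. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs, leaving out shallower cells, with B cells as a class that should lack the gene.

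Genes were named by a rule: per class and day, the 5 highest and the 5 lowest by the interval bound nearest to 1, among genes with at least 50 UMIs in the library where they are higher and a CPM there of at least 0.2 of the highest CPM in any other class of at least 30 cells. This last condition is meant to keep out RNA that comes from other cells. The macrophage class was taken as a whole and also as its alveolar and its interstitial or monocyte-derived part, and these 2 parts were not set against each other in that condition. Set against the other part, 5 of the 20 entries of alveolar macrophages would not have met it (C1qb at day 14, C1qc at both days, and C1qa and Arg1 at day 28, at 0.0786 to 0.164 of the level in the other part), and 0 of the 20 of interstitial or monocyte-derived macrophages. Other classes with at least 300 cells in each library (B cells, dendritic cells and monocytes) had 3 per side. Predicted genes, mitochondrial, ribosomal and haemoglobin genes and receptor segments were left out. Other genes in the text are members of the fixed lists, picked as examples after their values were seen. Gene positions are those of GENCODE M21 on GRCm38, the assembly also called mm10. Software was Python 3.11.15, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 for other scale factors.

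The 15 other settings fixed beforehand changed the cell filter, the doublet step, the clustering, the scaling, the depth per cell or the minimum count, and 3 more were added after seeing the data. TMM factors would shift all log2 ratios of the alveolar epithelial class by -0.32 (day 14) and -0.23 (day 28) and those of the interstitial or monocyte-derived macrophages by 0.27 and 0.13; the macrophage class as a whole and the alveolar macrophages shift by 0.15 at day 14. In simulated class sums with 200 changed genes, the criterion for a higher or lower gene recovered 92.5% (day 14) and 92.4% (day 28) of 2-fold changes in fibroblasts, 90.5% and 77.3% in T cells and 63.1% and 63.5% in the alveolar epithelial class. The intervals held the true ratio for 95.4% to 96.6% of genes, and 1.07% to 2.57% of unchanged genes were called. The simulation draws counts at random and so covers counting error, not differences between mice.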

Results

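Bleomycin, a drug that breaks DNA, injures the lung and is widely used in mice to model pulmonary fibrosis. The data are single-cell transcriptomes of whole lung from C57BL/6 mice without bleomycin (control) and at day 14 and day 28 of the bleomycin model. Each group is 1 library, made from equal numbers of cells of 3 mice mixed after enzymatic digestion, so there is no replicate and every difference below is a difference between 2 pooled libraries. After filtering, the control library has 11240 cells with a median of 3355 UMIs, day 14 has 10002 cells with 5294 and day 28 has 15038 cells with 3915. Intervals in brackets are exact 95% intervals of counting error. Both days are set against the same control library, so chance features of that library appear in both comparisons.

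The make-up of the cell suspension differed between control and bleomycin in macrophages, neutrophils, lung epithelium and NK cells, among others. Cells resembling interstitial or monocyte-derived macrophages were 2.33% of control cells and 16.0% and 15.6% of cells at day 14 and day 28, ratios of 6.88 [6.04 to 7.88] and 6.68 [5.88 to 7.62]. These ratios depend on the clustering: they were 3.84 [3.36 to 4.40] and 4.66 [4.12 to 5.30] with each library clustered alone, and 9.54 and 8.79 with every response gene left out, a setting added after the data had been seen. All macrophages together were 22.5%, 32.5% and 36.0% (control, day 14, day 28), and alveolar macrophages alone 20.2%, 16.5% and 20.4%. Neutrophils were 2.38%, 6.66% and 6.66%, with the same ratio of 2.79 at both days, and monocytes 4.49%, 7.46% and 6.01%. Alveolar epithelial cells, which line the gas exchange surface, were 3.92% of control cells and 0.620% and 0.499% after bleomycin (ratios 0.158 and 0.127). NK cells were 3.89%, 0.590% and 0.565%, mural cells of vessels and airways 2.93%, 0.760% and 1.02%, and airway epithelial cells 1.18%, 0.350% and 0.286%. With each library clustered alone, alveolar epithelial cells had ratios of 0.251 and 0.219 and NK cells of 0.226 and 0.0972, mural cells were 7.35%, 0.680% and 1.46%, and no cluster of either bleomycin library was named airway epithelial. The alveolar clusters of both bleomycin libraries carry airway genes in that setting, so their ratios may include airway cells. At resolution 0.5 mural cells were 6.87%, 1.10% and 1.61%. Vascular endothelial cells were 17.8%, 9.21% and 10.5%. Fibroblasts were 9.61%, 5.82% and 10.6%, 0.606 of the control share at day 14 and 1.10 of it at day 28.

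The remaining classes were T cells (11.9%, 16.8% and 12.5%), B cells (7.41%, 9.69% and 6.69%), dendritic cells (3.83%, 4.53% and 3.14%), cycling cells of mixed origin (1.92%, 2.75% and 3.50%), group 2 innate lymphoid cells (0.952%, 0.450% and 0.532%), plasma cells (0.418%, 0.750% and 0.432%) and lymphatic endothelial cells (0.498%, 0.450% and 0.313%). Mesothelial cells numbered 7, 21 and 2. Unnamed cells were 4.29%, 0.420% and 0.758%, and 480 of those in control lie in 1 cluster with mural and capillary endothelial markers alike. In all, 5 classes at day 14 and 3 at day 28 had a share at least 1.5-fold above control, and 7 at each day at least 1.5-fold below, counting only named classes whose interval excludes 1. The monocyte share is below control at both days under other cell filters, a coarser clustering or fewer clustering genes. At resolution 0.5 it is 4.30%, 2.48% and 1.00%, with ratios of 0.577 [0.493 to 0.674] and 0.234 [0.193 to 0.281], so its direction is not settled. The plasma cell ratio at day 14 is not settled either. It is 1.79 in the main setting, 1.47 [0.982 to 2.20] at resolution 0.5 and 0.853 [0.605 to 1.20] with every response gene left out. With the first naming rule T cells would be 7.44%, 12.0% and 9.57% and unnamed cells 10.9%, 5.72% and 4.29%.

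**Figure D1:**
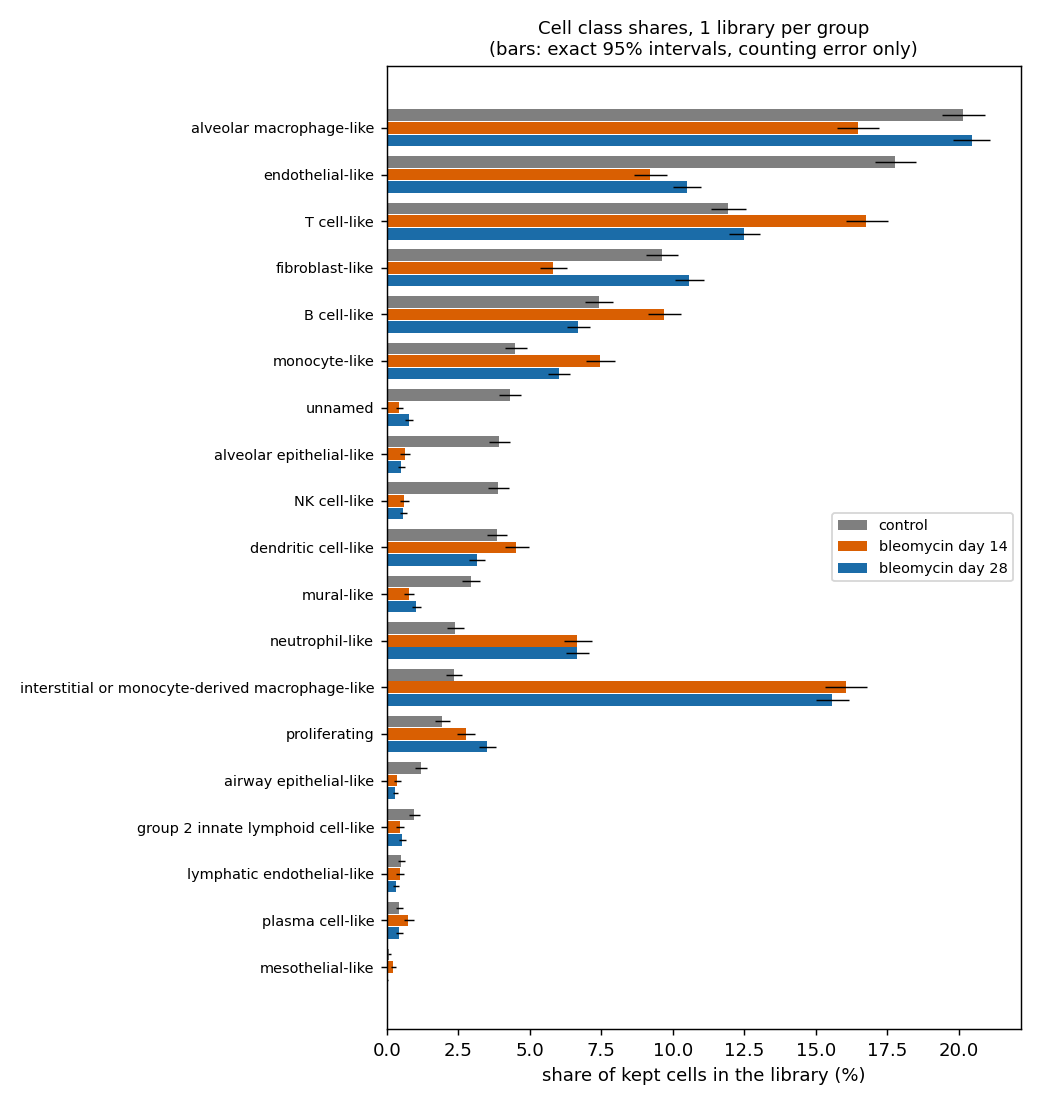
Share of cells (%) in each named class for the control, day 14 and day 28 libraries, with 1 bar per library and exact 95% binomial intervals as error bars. Interstitial or monocyte-derived macrophages stand at 2.33% in control and at 16.0% and 15.6% after bleomycin, while alveolar epithelial and NK cells are below 1% in both bleomycin libraries.

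Most of the listed genes of activated fibroblasts were at higher levels in fibroblasts of both bleomycin libraries than in control fibroblasts. Spp1 (chr5:104435118-104441050, plus strand), which encodes the secreted matrix protein osteopontin, was at 1.94 CPM in control fibroblasts and at 6311 and 6034 CPM at day 14 and day 28, ratios of 3255 [1903 to 6114] and 3112 [1820 to 5845]. Grem1 (chr2:113746164-113758646, minus strand), an antagonist of bone morphogenetic proteins, had 1 UMI in control fibroblasts and 530 and 374 CPM after bleomycin (3554-fold [638 to 140399] and 2510-fold [450 to 99162]). Cthrc1 (chr15:39076932-39087121, plus strand), a secreted protein of injured and fibrotic tissue, was 189-fold [95.6 to 438] and 127-fold [64.4 to 295] higher, and Postn, the matricellular protein periostin, 57.0-fold and 95.1-fold. Acta2, the smooth muscle actin of myofibroblasts, was 10.3-fold [9.33 to 11.3] and 13.5-fold [12.2 to 14.8] higher. The day 28 folds depend on which cells are called fibroblasts. With each library clustered alone the class has 1352 instead of 1590 day 28 cells, and an unnamed cluster of 246 day 28 cells has Tnn, Hmga2, Cthrc1, Postn and Acta2 among its leading genes. In that setting the day 28 log2 ratio of Hmga2 in fibroblasts is 5.79 instead of 8.71 and that of Tnn 6.65 instead of 7.99, and 18 activated fibroblast genes are higher instead of 20. Cthrc1, Postn and Acta2 were not computed in it.

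Of 24 measured genes of activated fibroblasts, 19 were higher and 0 lower at day 14, and 20 higher and 3 lower (Tgfbi, Itgbl1 and Loxl1) at day 28, with median log2 ratios of 3.43 and 3.44 (percentile 100 of the matched random lists at both days). Timp1, an inhibitor of matrix metalloproteases, was 11.4-fold and 9.70-fold higher. Of 20 fibrillar collagens and associated matrix genes, 14 were higher at day 14 and 12 at day 28 (medians 1.11 and 1.22; 1 and 3 lower). Among them Col1a1 was 3.00-fold [2.97 to 3.04] and 3.71-fold [3.67 to 3.76] higher, Fn1 6.87-fold and 7.99-fold and Col12a1 7.50-fold and 8.77-fold, whereas Col14a1 was 2.63-fold and 5.89-fold lower. Matrix proteases and inhibitors had 11 and 12 of 22 higher. Cell cycle genes were higher for 22 and 21 of 22 (medians 2.91 and 2.97), with Mki67, a proliferation marker, at 13.4, 75.6 and 76.0 CPM. Basement membrane genes (4 higher and 6 lower of 19 at day 14; 6 and 6 at day 28) and TGF-beta signalling genes (5 higher and 6 lower of 20 at each day) went both ways. Glycolysis and hypoxia genes were higher for 11 and 12 of 20.

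Genes of alveolar fibroblasts, the resident cells that sit next to the air sacs, were lower for 18 of 19 at both days, with medians of -1.73 and -2.19 and no member higher. Inmt, a methyltransferase of small amines, was 14.1-fold [13.6 to 14.6] and 12.2-fold [11.8 to 12.5] lower, Npnt, an integrin ligand of the basement membrane, 5.21-fold and 4.51-fold, and Tcf21, a mesenchymal transcription factor, 7.04-fold and 6.57-fold. The rule for named genes further gives, as higher, Hmga2 (712-fold [197 to 5879] and 419-fold [116 to 3465]), a chromatin protein; Thbs4 (at least 240-fold and at least 411-fold) and Tnn (122-fold and 255-fold), both matricellular proteins. Cfd and Car3, genes of adipocytes, were high at day 14 alone: Cfd at 684 CPM, at least 1530-fold above control, with 0 UMIs in control and day 28 fibroblasts, and Car3 at 379 CPM against 0.149 and 0.0635. As lower it gives Colq (115-fold and 24.1-fold), Colgalt2 (86.9-fold and 32.1-fold), Mapt, Iyd, Edn3, Angptl7 and Kcna2, these last 5 between 4.91-fold and 169-fold lower over the 2 days.

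The share of fibroblasts with a Cthrc1 UMI at 1000 UMIs per cell was 0.191% in control, 10.7% at day 14 and 8.31% at day 28, after leaving out 32, 0 and 134 shallower fibroblasts, with 0% of B cells in each library (upper limits 0.479%, 0.438% and 0.485%). For Acta2 it was 4.39%, 27.7% and 32.6%, against 0.520%, 0.833% and 0.528% of B cells. Median UMIs before thinning were 5852.5, 13842.5 and 9000.0 in fibroblasts and 1909, 1488 and 1298 in B cells. Free RNA was present: Spp1 stood at 2.37, 311 and 226 CPM in B cells, genes of lipid-handling macrophages were higher in fibroblasts too (16 of 24 at each day), and collagen genes were higher in B cells (10 of 12 and 8 of 9). The fibroblasts come from different clusters in each group, cluster 12 in control (858 of 1080 cells) and cluster 9 after bleomycin (340 of 582 and 1219 of 1590), and genes that respond to dissociation and heat shock were lower in them after bleomycin (medians -1.27 and -1.07).

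The alveolar epithelial class had lower surfactant genes and higher genes of injured, transitional epithelium after bleomycin. Sftpc (chr14:70520949-70524081, minus strand), the surfactant protein that marks type 2 cells, was 11.0-fold [10.6 to 11.4] lower at day 14 and 4.67-fold [4.53 to 4.80] lower at day 28, and Lyz1, a lysozyme of type 2 cells, 250-fold [121 to 622] and 20.6-fold [15.8 to 27.3]. Of 20 surfactant and type 2 identity genes, 20 and 18 were lower and 0 higher (medians -2.76 and -1.71). Cldn4 (chr5:134945119-134946934, minus strand), a tight junction protein, was 457-fold [177 to 1685] and 340-fold [131 to 1259] higher. Krt8, a keratin of the transitional state, was 4.52-fold [3.79 to 5.39] and 5.07-fold [4.18 to 6.13] higher. Transitional epithelial genes were higher for 20 of 21 and 19 of 20 (medians 3.01 and 2.61), among them Sfn (14.3-fold and 12.2-fold) and Krt19 (5.62-fold and 6.39-fold). Targets of p53, the transcription factor of the DNA damage response, were higher for 16 of 19 and 13 of 17 (2.60 and 1.69), including Cdkn1a, an inhibitor of the cell cycle (8.04-fold and 6.08-fold), and Mdm2, the negative regulator of p53 (15.7-fold and 3.37-fold).

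This class merges type 1 and type 2 cells, whose proportions differ between the libraries. In a finer clustering the cluster led by type 2 markers had 308, 6 and 15 cells (2.74%, 0.06% and 0.0997%) and the cluster led by type 1 markers 134, 57 and 61 (1.19%, 0.570% and 0.406%). Within the latter, taken alone only after the data had been seen, the surfactant list turned: 11 of 16 genes were higher at day 14 and 13 of 16 at day 28, with 0 lower (medians 1.07 and 2.05). The lower surfactant levels hold for the merged class and were not seen within the type 1 cluster. Transitional genes (19 of 21 and 17 of 20 higher, 2.98 and 2.57) and p53 targets (16 of 19 and 11 of 14, 2.30 and 1.45; Fas lower at day 14) were higher there as well. Airway genes are present too: Scgb1a1, the secretoglobin of airway club cells, was at 610, 2628 and 3525 CPM in the merged class, against 350, 26.0 and 23.4 CPM in B cells. With each library clustered alone, the alveolar clusters of day 14 (93 cells) and day 28 (122 cells) have Scgb1a1 and Cyp2f2 among their leading genes. No bleomycin cluster is named airway epithelial in that setting. These clusters may therefore hold the airway cells that the main setting keeps apart (35 and 43), and they say little about the merged class. Given the Scgb1a1 levels in the merged class, airway cells in it are not ruled out as a part of the higher transitional genes.

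The rule for named genes in the merged class gives, as higher, Basp1 (260-fold and 47.2-fold), Cldn6 (at least 83.3-fold at day 14), Tnip3 (88.8-fold and 25.8-fold), a regulator of NF-kappaB, and Ly6g6c (99.9-fold and 432-fold). Resp18 (102-fold and 127-fold), Scg2 (8.33-fold and 59.6-fold) and Calca (11.2-fold [8.47 to 14.8] and 31.3-fold [24.2 to 40.9]), proteins of neuroendocrine secretory granules, were also higher. As lower it gives Cpm (carboxypeptidase M), Hc (complement C5), Acoxl, Sftpa1, Cped1 and Aox3, between 3.66-fold and 49.1-fold lower over the 2 days. The share of cells with a Krt8 UMI at equal depth was 6.65%, 22.6% and 35.3% (0% of B cells) and with a Cdkn1a UMI 16.6%, 48.4% and 51.5% (1.30%, 1.43% and 2.77% of B cells), with median depths of 5428, 6755.5 and 3941 UMIs. At 500 UMIs per cell the Krt8 shares lay closer together, at 5.54% [3.58 to 8.14], 9.68% [3.63 to 19.9] and 12.0% [5.64 to 21.6], with overlapping intervals. The class holds 441, 62 and 75 cells. Markers of alveolar fibroblasts were lower in it too (13 of 15 at both days), and the dissociation and heat shock genes had medians of -0.17 and 0.08.

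Macrophages of both bleomycin libraries expressed genes of lipid-handling, profibrotic macrophages. Arg1 (chr10:24915221-24927484, minus strand), an enzyme that turns arginine into ornithine, had 3 UMIs in control macrophages and 648 and 355 CPM after bleomycin, 4367-fold [1494 to 21176] and 2390-fold [818 to 11593] higher. Spp1 was at 252, 10770 and 9346 CPM (42.8-fold [41.6 to 44.0] and 37.1-fold [36.1 to 38.2]). Gpnmb, a lysosomal glycoprotein, was 4.64-fold and 3.61-fold higher, Trem2, a lipid receptor, 7.34-fold and 7.58-fold, and Mmp12, the macrophage elastase, 19.4-fold and 17.7-fold. The proportions of the 2 macrophage parts differ between libraries, and within each part the folds of Trem2 and Mmp12 were smaller: Mmp12 was 3.48-fold and 9.74-fold higher in alveolar and 3.27-fold and 3.30-fold in interstitial or monocyte-derived macrophages, and Trem2 5.19-fold and 5.86-fold in the former and 2.96-fold and 3.22-fold in the latter. Gpnmb was 1.75-fold and 2.48-fold higher in the former and 65.4-fold and 44.0-fold in the latter. Of the 24 genes of this list 18 were higher at day 14 and 17 at day 28 (medians 2.30 and 2.23), with Plin2 lower at day 14 and Cd36 lower at day 28. Identity genes of alveolar macrophages were lower for 15 and 12 of 20 (-1.29 and -1.16), such as Ear1, an eosinophil-associated ribonuclease (19.3-fold and 11.7-fold), and Siglecf, a sialic acid receptor (4.30-fold and 6.99-fold).

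Inflammatory cytokine and chemokine genes went both ways (10 higher and 7 lower of 27 at day 14; 11 and 8 at day 28). Ccl2, which attracts monocytes, was 8.32-fold and 9.94-fold higher, whereas Cxcl2, which attracts neutrophils, was 3.52-fold and 3.67-fold lower and Tnf 1.87-fold and 2.47-fold lower. Alternative activation genes were likewise divided (7 higher and 8 lower of 17; 4 and 7), and complement genes were higher for 8 and 7 of 18. The named genes add Syngr1 (194-fold and 147-fold), Npy (at least 87.9-fold and at least 120.2-fold), Slc36a2, Adam8, a membrane metalloprotease (71.9-fold and 69.1-fold), and Htr2b, a serotonin receptor (250-fold [44.7 to 9882] and 406-fold [72.7 to 16051]). Lower were Fabp1, a fatty acid binding protein (106-fold and 46.8-fold), Krt4, Spag11b, Acaa1b and Krt79. The values in this paragraph are of the merged macrophage class and so mix levels per cell with the proportions of its 2 parts. The lower named genes were also named as lower within alveolar macrophages alone.

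Within alveolar macrophages alone the lipid-handling list was higher for 18 of 24 at both days (medians 1.48 and 2.08) and identity genes lower for 10 and 11 of 20. C1qb (chr4:136880129-136886187, minus strand), a chain of complement C1q, was 136-fold [107 to 175] and 253-fold [199 to 326] higher, with C1qc and C1qa alongside (69.7-fold and 133-fold; 92.4-fold and 125-fold). C1qb stood at 3.60, 490 and 910 CPM in this class, at 4830, 3124 and 3592 CPM in interstitial or monocyte-derived macrophages, at 2.96, 53.7 and 74.0 CPM in B cells and at 2.41, 105 and 167 CPM in neutrophils. A part of these folds from RNA of the other macrophages is not ruled out. Cxcl3 was 32.7-fold and 8.22-fold lower. Antigen presentation genes of MHC class II were higher for 8 of 13 at each day, with H2-Ab1 4.84-fold and 3.96-fold higher. Within interstitial or monocyte-derived macrophages the lipid-handling list was higher for 20 and 19 of 24 (2.21 and 2.03), but MHC class II genes were lower for 11 of 12 at both days, with H2-Ab1 6.85-fold [6.73 to 6.97] and 8.57-fold [8.41 to 8.73] lower. Their named genes were Spp1 (1536-fold and 1083-fold), Arg1, Fn1 (93.9-fold and 96.3-fold), Fabp5 (97.6-fold and 61.6-fold), Gpnmb and Saa3 as higher and Siglech, St8sia6, P3h2, Asb2, Ildr2, Ifi206 and Retnla as lower. Glycolysis (13 and 15 of 19) and oxidative phosphorylation genes (15 and 13 of 20) were higher in them.

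At equal depth 16.2% of control macrophages had an Spp1 UMI, against 80.7% and 81.5% at day 14 and day 28, with 0.130%, 24.9% and 18.5% of B cells. For Arg1 the shares were 0% (upper limit 0.149%), 24.3% and 11.8%, and 0%, 0.952% and 0.923% of B cells. Macrophages had median depths of 7931, 13691 and 7633.5 UMIs. The cells of each group lie in different clusters: alveolar macrophages in cluster 4 in control (2235 of 2265) and cluster 0 after bleomycin (1633 of 1648 and 2962 of 3075), and interstitial or monocyte-derived macrophages in cluster 3 in control and in clusters 3 and 7 after bleomycin. Dissociation and heat shock genes were lower in macrophages after bleomycin (medians -1.06 and -1.0). Collagen genes were higher in macrophages (15 of 19 at both days), as in fibroblasts and B cells. The alveolar epithelial class did not share this for Col1a1 (146, 71.7 and 149 CPM) or Col3a1 (123, 47.3 and 55.5 CPM).

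The endothelial class as a whole had lower capillary genes and higher genes of activated or venous vessels. Of 22 capillary genes 11 and 12 were lower and 0 higher (medians -0.59 and -0.63), with Car4, a carbonic anhydrase of the capillary surface, 1.62-fold and 1.68-fold lower and Plvap, a protein of endothelial diaphragms, 1.82-fold and 1.5-fold. Of 22 activated or venous genes 13 and 10 were higher and 4 lower at each day (0.80 and 0.45): Lrg1, a leucine-rich glycoprotein, was 9.95-fold [9.20 to 10.8] and 9.46-fold [8.75 to 10.2] higher, Col15a1 6.34-fold and 3.59-fold and Selp, the adhesion molecule P-selectin, 3.60-fold and 2.89-fold, while Vcam1 was 2.45-fold and 1.57-fold lower. Cyp1a1 (chr9:57687928-57703824, plus strand), a cytochrome P450 induced by the aryl hydrocarbon receptor, was at 2037 CPM in control and 67.5-fold [55.5 to 82.9] and 13.8-fold [12.6 to 15] lower. Glycolysis and hypoxia genes were higher for 13 of 19 at both days (0.89 and 1.04), for example Slc2a1, a glucose transporter (5.10-fold and 3.69-fold). Cell cycle genes were higher for 15 of 22 at day 14 (0.98) and for 3 of 21 at day 28 (-0.28), with Top2a at 26.7, 71.6 and 20.5 CPM.

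The named endothelial genes also include, as higher, Vwa1 (30.8-fold and 14.7-fold), Ackr1, a chemokine-binding receptor of venules (104-fold [18.0 to 4166] and 194-fold [34.2 to 7710]), Ankrd37 (22.4-fold and 40.2-fold), Serpina3m, Dbp, a clock-controlled transcription factor (24.5-fold and 30.3-fold), and H19, an imprinted noncoding RNA (67.8-fold [22.8 to 333] at day 28). As lower they include Slc5a12, Cytl1, Kif26b, Fibin, Gbp6, Gbp10, Cmpk2 and Ifi44, the last 4 interferon-inducible, between 1.89-fold and 20.4-fold lower over the 2 days. Control endothelial cells lie mostly in cluster 8 (1323 of 1999) and those after bleomycin in cluster 6 (704 of 921 and 961 of 1577). Cluster 8 has Tmem100, Sema3g and Plvap among its leading genes, and cluster 6 has Vwf, Ackr3 and Edn1. The endothelial values therefore mix levels per cell with the proportions of these clusters. Dissociation and heat shock genes had medians of -0.71 and -0.63, and alveolar fibroblast genes, markers of another class, were lower here as well (11 of 13 and 10 of 12).

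T cells had higher activation and regulation genes and lower cytotoxicity genes. At day 14, 17 of 22 activation and regulation genes were higher and 0 lower (median 1.60), and at day 28, 9 of 20 were higher and 1 lower (0.46). Foxp3, the transcription factor of regulatory T cells, was 6.93-fold [5.69 to 8.51] and 2.57-fold [2.04 to 3.25] higher, Tnfrsf9 and Tnfrsf4, costimulatory receptors, 19.8-fold and 4.23-fold and 17.8-fold and 7.75-fold, and Pdcd1, the inhibitory receptor PD-1, 8.64-fold and 8.10-fold. Cytotoxicity genes were lower for 11 and 13 of 20, with 1 (Ctsw) and 0 higher (medians -0.66 and -0.84); the granule proteases Gzma and Gzmb were 3.65-fold and 5.02-fold and 2.10-fold and 6.84-fold lower. Cell cycle genes were lower for 11 and 20 of 22. The other named genes were Penk, the enkephalin precursor (113-fold [30.8 to 936] and 56.1-fold [15.1 to 471]), Tff1, Tnfrsf8, Neb and, at day 28, the cytokine Il17f (16.6-fold [6.73 to 52.8]) as higher, and Hsph1, Art2b, Dtx1, H2-T24, Usp18, Ifi27l2a, Mx1, Kif18b and Ccnb2 as lower.

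The T cell class joins 4 clusters in each library, among them a CD8 cluster of 506, 481 and 441 cells and a gamma-delta cluster of 134, 115 and 248. Another, of 101, 210 and 95 cells, has Foxp3 but also Gzmb, Mki67 and Top2a among its leading genes. These numbers are therefore not a count of regulatory T cells. The values of the T cell class mix levels per cell with the proportions of these clusters. Under the first naming rule, which leaves the CD8 cluster out, 3 cytotoxicity genes were higher at day 14 and 1 at day 28. Macrophage genes of the lipid-handling list were higher in T cells as well (14 of 21 and 13 of 22), with Spp1 at 4.03, 249 and 249 CPM, and dissociation and heat shock genes were lower (medians -0.46 and -0.89).

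Among the other classes, B cells had 16.6-fold and 5.51-fold more Ighg3, an immunoglobulin G constant region, 9.78-fold and 8.27-fold more Tbc1d9, with Cdh17 and Il9r also higher, and less Sox4, Ifi27l2a, Ifit2, Oas2 and Slfn5. The immunoglobulin constant and plasma cell list as a whole had 6 higher and 4 lower of 18 in B cells at day 14 and 5 and 1 at day 28. Dendritic cells had 53-fold [34.1 to 87] and 33.0-fold [21.2 to 54.5] more Ifitm1, an interferon-inducible membrane protein, and more Mucl1 (at day 14), Cyp7b1, Ffar2, Ndrg4 and Slc7a5, and less Ccdc170, Naalad2, Xlr, Atf3 and Hspa1b. Monocytes had at least 130.1-fold and at least 153-fold more Arg1, with AA467197, Mmp14, Pf4 and Emp1 also higher, and less Ly6c2, a marker of classical monocytes (8.14-fold and 31.1-fold), Cd300e, Tmem26, Ifi44 and Phf11a. Lipid-handling genes were higher in monocytes for 20 and 19 of 24. Mural cells had more matrix genes (19 and 16 of 20 higher), with Col1a1 5.33-fold [5.03 to 5.64] and 5.54-fold [5.25 to 5.85] higher. Over all cells together, naive lymphocyte genes were lower for 11 and 10 of 15. Control and bleomycin monocytes lie mainly in different clusters (487 of 505 control cells in cluster 16; 506 of 746 and 772 of 904 in cluster 11).

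Interferon-stimulated genes, the antiviral genes induced by interferons, were lower after bleomycin in most classes. At day 14 and day 28 they were lower for 20 and 24 of 27 in fibroblasts (medians -1.24 and -1.67), 22 and 24 of 26 in endothelial cells (-1.20 and -1.47), 20 and 21 of 26 in T cells (-0.87 and -1.38), and 22 of 25 and 21 of 24 in B cells (-1.85 and -1.93). Ifit3, an antiviral protein, was 4.39-fold [3.91 to 4.95] and 5.66-fold [5.09 to 6.30] lower in fibroblasts and 4.43-fold and 6.67-fold in B cells, and Isg15, a ubiquitin-like protein, 6.29-fold and 2.82-fold in endothelial cells. Neutrophils (20 and 21 of 22 lower), monocytes (23 and 25 of 27) and interstitial or monocyte-derived macrophages (24 and 26 of 27) went the same way. So did dendritic cells (16 of 27 and 19 of 26 lower). Alveolar macrophages did not: 17 and 10 of 27 were higher there (0.81 and 0.42). In the merged macrophage class 16 of 27 were higher at day 14. Cycling cells had 19 of 27 higher at day 14 and 5 of 22 at day 28, and the alveolar epithelial class 4 higher and 4 lower of 23 at day 14 and 10 of 21 lower at day 28. Group, mouse pool and library cannot be told apart, and 1 control pool stands behind all of these ratios.

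**Figure D2:**
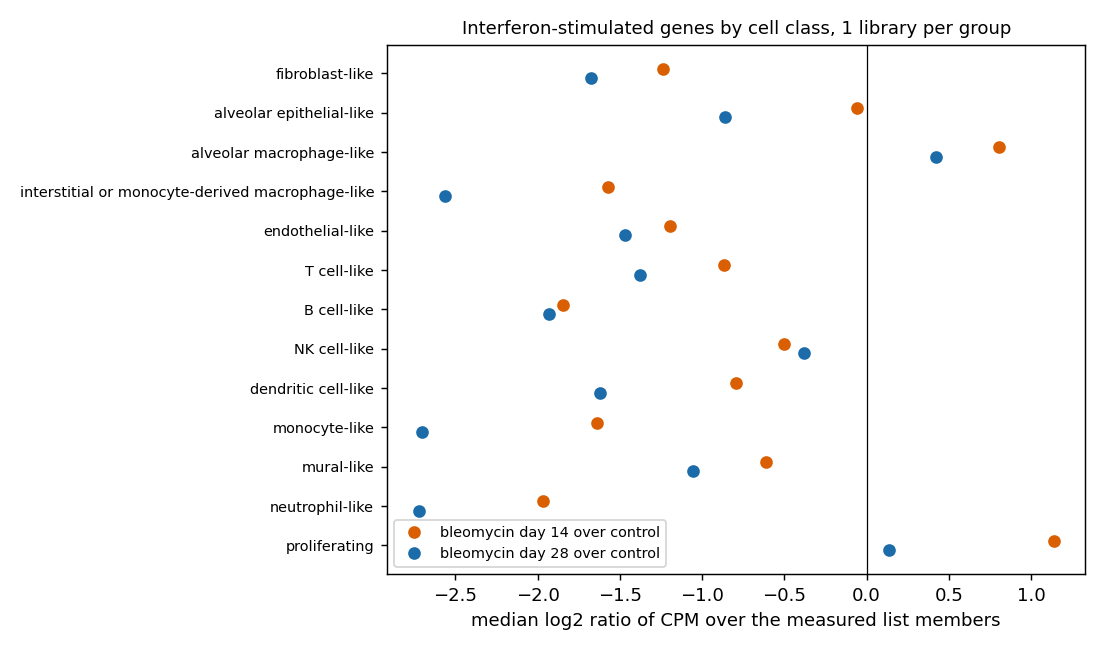
Median log2 ratio of the interferon-stimulated genes against control for each cell class, at day 14 and day 28. The values of fibroblasts, endothelial cells, T cells and B cells lie between -0.87 and -1.93, and alveolar macrophages and cycling cells lie above 0 at both days.

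Between the bleomycin libraries, the matrix and activation lists of fibroblasts differed little in their medians, while single genes went either way. The median log2 ratio of day 28 over day 14 was 0.03 for collagens and associated matrix and -0.07 for activated fibroblast genes. Postn was 1.67-fold [1.58 to 1.75] higher and Cthrc1 1.49-fold [1.40 to 1.58] lower at day 28. The fibroblast share was 1.82 times that of day 14. In the alveolar epithelial class 16 of 19 surfactant genes were higher at day 28 (median 1.15), with Sftpc 2.35-fold [2.25 to 2.46] higher. In the finer clustering, the cluster led by type 2 markers had 6 cells at day 14 and 15 at day 28. The cluster led by type 1 markers had 57 and 61. These surfactant ratios therefore mix levels per cell with the proportions of few cells. Of the p53 targets in this class, 9 of 19 were lower (-0.65), with Mdm2 4.67-fold [3.54 to 6.28] lower. In T cells 14 of 22 activation and regulation genes were lower and 0 higher (-0.93), with Tnfrsf9 4.69-fold [3.77 to 5.89] and Foxp3 2.70-fold [2.32 to 3.15] lower. In macrophages Arg1 was 1.83-fold [1.79 to 1.86] lower and Retnla, a product of alternatively activated macrophages, 10.5-fold [9.19 to 11.9] lower, and in endothelial cells 13 of 22 cell cycle genes were lower (-1.06).

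**Figure D3:**
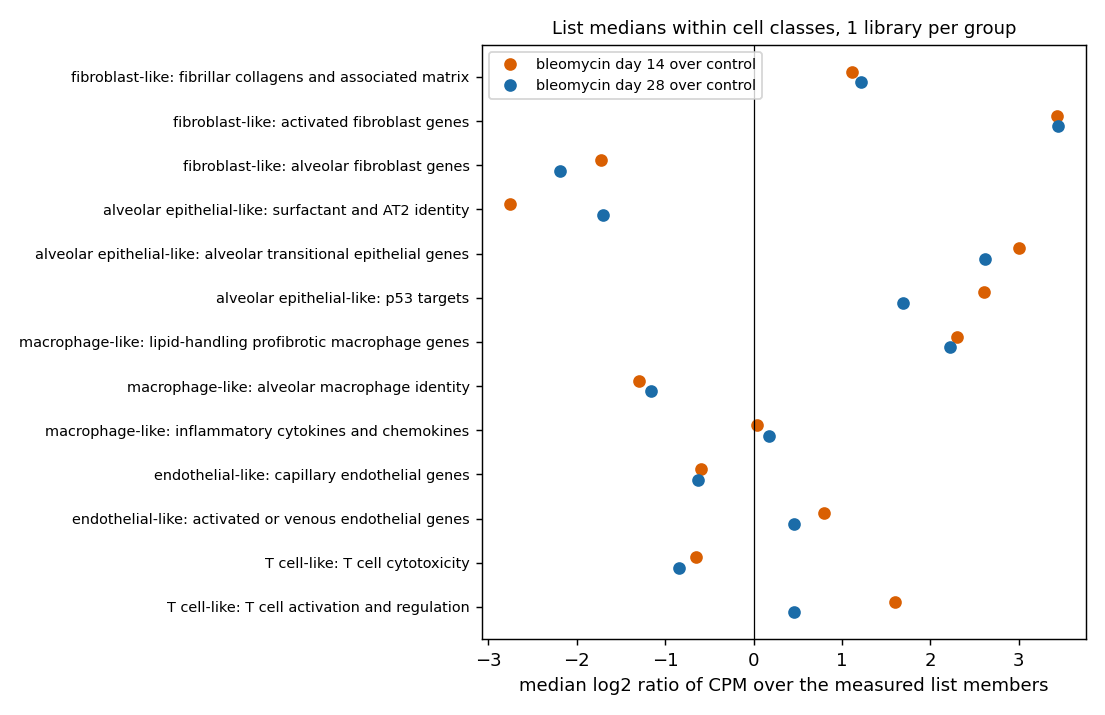
Median log2 ratio against control of the gene lists fixed for each cell class, at day 14 and day 28. Activated fibroblast, transitional epithelial and lipid-handling macrophage lists lie above 2 at both days, and the surfactant list of the merged alveolar epithelial class lies at -2.76 and -1.71. The type 1 cluster, in which the surfactant medians were positive, is not drawn.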

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

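No paired analysis was possible because each group is 1 pooled library, and for the same reason no library could be left out in turn and no other split of the samples exists. The settings named here were fixed beforehand, except 3 chosen after seeing the data: leaving every response gene out of the clustering, the first naming rule, and the type 1 cluster alone. Scaling changed no direction: of 200 results, 189 under TMM factors and 190 under median-of-ratios size factors stayed within counting error or within 1.5-fold of their count, and the others moved without turning. A minimum of 100 UMIs moved 1 of 184 and no minimum moved 0 of 200. Mean CPM per cell moved 36 of 200, and cells thinned to 1000 UMIs 88 of 179, none turning. Doublets kept (29 of 242), response genes kept (16 of 242), resolution 2 (15 of 244) and the first naming rule (6 of 240) also turned none. Without thinning, or at 500 UMIs, 16 of 18 shares of cells with a UMI moved and 0 turned, since a share with a UMI depends on depth.

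A result counts as turned only if it was at least 1.5-fold before. By that rule 2 of 243 turned with each library clustered alone, 2 of 244 with every response gene left out, 1 of 244 without a cell filter, 1 of 244 with the strict filter and 1 of 240 at resolution 0.5. The log2 ratio of the monocyte share at day 14, 0.73, became -0.40 under the strict cell filter, -0.69 without a cell filter, -0.79 at resolution 0.5 and -0.77 with every response gene left out. At day 28 it was 0.42, too small to count, and became -2.12, -1.97, -2.10 and -2.32 in the same 4 settings. With every response gene left out the plasma cell share at day 14 became -0.23 instead of 0.84 and that at day 28 became 1.77 instead of 0.05, and with each library clustered alone these were at least 4.14 and at least 3.72, with 0 such cells in control. Classes at least 1.5-fold higher in share at day 14 were 3, not 5, at resolution 0.5 and also 3 with every response gene left out. With each library clustered alone the unnamed share became at least 6.03 at day 14 and at least 5.94 at day 28, as control had 0 such cells, against -3.35 and -2.50; these are 175 day 14 cells led by gamma-delta T cell genes and 246 day 28 cells led by genes named for fibroblasts. Small share ratios also changed sign: alveolar macrophages at day 14 (-0.29) became 0.05 under the strict filter and 0.31 without a filter, and fibroblasts at day 28 (0.14) became -0.02 at resolution 2 and -0.11 with each library clustered alone. The cause of these changes was not tested. Under the first naming rule, which by construction leaves out the CD8 cluster, 3 rather than 1 T cell cytotoxicity genes were higher at day 14 and 1 rather than 0 at day 28. Within the type 1 cluster, which leaves out the cells led by type 2 markers, 11 surfactant genes were higher at day 14 and 13 at day 28 instead of 0, the list medians became 1.07 and 2.05 instead of -2.76 and -1.71, and the log2 ratios of Hc at day 14 and Lyz1 at day 28 became 0.38 and 4.71. The alveolar epithelial and NK classes have only 62 and 59 cells at day 14.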

Other observations

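Mural cells, which wrap vessels and airways, had higher matrix genes and lower contractile actin. Timp1 was 58.8-fold and 58.6-fold higher (day 14, day 28), Tnc, the matricellular protein tenascin C, 9.48-fold and 7.58-fold, and Fn1 8.12-fold and 11.7-fold, while Acta2 was 2.32-fold and 2.45-fold lower. The class joins cluster 23, with Actc1, Myh11 and Acta2 among its leading genes (236, 49 and 90 cells), and cluster 28, led by Hhip and Enpp2 (93, 27 and 64). Its values mix levels per cell with the proportions of these clusters. A part of the matrix genes from free RNA is not ruled out. The monocyte class had higher MHC class II genes (10 and 8 of 12) and inflammatory genes (16 and 12 of 23) after bleomycin. The MHC class II genes of interstitial or monocyte-derived macrophages went the opposite way. Most control monocytes lie in cluster 16 and most bleomycin monocytes in cluster 11, which has H2-Ab1, H2-Aa and H2-Eb1 among its leading genes. Cluster 7 of those macrophages has no control cell. The contrast therefore depends on which cells make up each class. Sftpc in B cells, a measure of free RNA of type 2 cells alone, was higher in control (46.3 CPM against 1.81 and 1.90). Scgb1a1 in B cells was higher in control as well (350, 26.0 and 23.4 CPM). Spp1 (2.37, 311 and 226 CPM) and Lyz2 (269, 1023 and 995 CPM) in B cells were higher after bleomycin. Free RNA therefore differed in kind between the libraries, and its total was not measured.

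In the patterns that follow, the tests of a shared shift, of the mouse pools, of the cell filter, of macrophage dilution and of dissociation yield, and the comparison with a single macrophage cluster, were chosen after the results had been seen. Spp1 levels in fibroblasts and macrophages were also known before their tests were run.

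Spp1 is high in fibroblasts of both bleomycin libraries and higher still in macrophages, so macrophage RNA was weighed first. If free RNA were the source, Spp1 and 5 macrophage genes (Mmp12, Trem2, Lyz2, Chil3 and Ctss) would stand in the ratio seen in B cells. That ratio was 21.7 times as high in fibroblasts at day 14 [19.8 to 23.8] and 35.8 times at day 28. Any of the 5 genes that B cells make themselves would inflate these folds, which was not tested. At day 14 fibroblasts had 6311 CPM of Spp1 and 1314 of Lyz2, and B cells 311 and 1023. At day 28 these were 6034 and 1141, and 226 and 995. Doublets of a fibroblast and a macrophage would bring the 5-gene ratio of interstitial or monocyte-derived macrophages, and fibroblasts exceeded it 10.1 times and 17.1 times (9.02 and 14.3 times for cluster 7, the macrophage cluster richest in Spp1). Both explanations are excluded as the main source, and that bleomycin fibroblasts transcribe Spp1 themselves is a hypothesis that may be followed up; it was not tested here, and in situ hybridisation of Spp1 together with a fibroblast marker in lung sections would decide it.

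Interferon-stimulated genes are lower in fibroblasts, endothelial cells, T cells and B cells of both bleomycin libraries. Thinning could not decide on unequal depth, because the CPM of UMIs summed over a class does not scale with the depth per cell. After thinning, the median log2 ratio nearest to 0 over these 4 classes and both days was -1.06. Stressed control cells were weighed by using only control cells low in dissociation genes. Dissociation genes were then no longer lower after bleomycin in endothelial, T and B cells (medians 0.01 to 0.74). The interferon list stayed lower in these classes, which argues against this explanation for them. Its value nearest to 0 was -0.87, in T cells at day 14. In fibroblasts dissociation genes stayed lower (-0.45 and -0.43), so the check cannot decide for them. A shift common to all cells of a library would lower the list in alveolar macrophages too, where it was higher at day 14 (0.81). These cells lie mostly in cluster 4 in control and in cluster 0 at day 14, so such a shift is not excluded. Control and bleomycin fibroblasts and endothelial cells also lie mainly in different clusters, and the effect of this on the list was not tested. Also open is a difference between the mouse pools other than bleomycin, such as an infection or cage effect in the control mice. The series has 1 control pool, so a lower interferon response after bleomycin could not be separated from such a difference.

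Alveolar epithelial, NK, mural and airway epithelial cells have lower shares in both bleomycin libraries. The filter, which removed far more barcodes from control, is argued against: without it the highest share ratio of the 4 classes was 0.418. A larger macrophage number in a fixed total is argued against by a highest ratio of 0.424 among cells other than macrophages. A lower yield of these cells from stiff fibrotic tissue may explain the shares as well as a loss of cells in the lung; 0 of the 3 libraries were made without enzymatic digestion, so these cannot be told apart.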
